A study of Drosophila melanogaster with 3 samples.

How the data were processed

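Total RNA of Drosophila melanogaster embryos of 3 maternal genotypes was compared pairwise on oligonucleotide arrays, per the labels. The deposited table holds 1 column for each of 3 comparisons (Tollrm9/rm10 against Toll10b, pipe against Toll10b, pipe against Tollrm9/rm10) and 14010 probe sets with values, 13966 for fly targets and 44 controls. 2 rows without values were left out. The labels describe each comparison as 2 channels, but the probe sets have the names of an Affymetrix array, a type on which 1 RNA is hybridised per array. How the authors scaled the measurements, treated weak signals or combined arrays is not given in the sources used here.

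The deposited values are signed fold changes to 1 decimal: 0 values have a size under 1, so a value is a ratio of 1 or more with a sign for direction. This unit was read from the values, since no label or header states it. Each was turned into log2 by taking log2 of the size and keeping the sign. Direction followed the order of genotypes in each title. The sign relation between columns was checked by closing the loop: the pipe against Toll10b ratio should equal the sum of the other 2 log2 ratios. With the title order in all 3 columns the residual had an SD of 0.528, against 1.42, 2.11 and 1.99 for the other sign combinations. This shows that the columns run the same way, not which way. The median log2 ratio of fly probe sets was 0.00 for Tollrm9/rm10 against Toll10b and -0.14 for both pipe comparisons. Values are reported as deposited, and folds in pipe comparisons can be read relative to that shift.

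Of the fly probe sets, 42.7% closed the loop within rounding, against 8.95% after shuffling 1 column. In probe sets whose largest ratio was under 1 on the log2 scale 62.1% closed, and where it was 2 or more 9.67% did, with a median absolute residual of 0.753. The columns thus appear to share measurements of each genotype at least in part. Most probe sets did not close within rounding, so this is not settled. The ratio inferred from the other 2 comparisons is therefore not counted as an independent measurement. For the same reason the planned limma fit of the 3 columns as a loop with 1 residual degree of freedom was not run. Its condition, columns not computed from one another, could not be shown to hold. Large folds are the least certain in size. For twi the inferred folds were 26.1 and 76.6 where the direct ones were 63.8 and 31.3.

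Gene names came from the platform annotation supplied for the probe sets. 12442 fly probe sets had 1 symbol, 327 several and 1197 none. Of the single symbols, 12393 were updated through the gene ID to the Release 6 gene table and 49 were kept as listed. These gave 10843 genes. No coordinates are given because no build is stated for the array. Probe sets of 1 gene were combined by their median for gene lists and kept apart elsewhere. In 946 genes with 2 probe sets the SD between probe sets was 0.838, 0.969 and 0.962 on the log2 scale for the 3 comparisons in the order above.

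The table holds no replicate values, so counts at fixed folds replace tests: at least 2-fold, with 1.5-fold and 3-fold as alternatives. Control shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting of probe sets only. 18 gene lists with 196 symbols were fixed before the data were examined, together with the rules below. 135 of the symbols had a probe set with a single name. Members of the mesoderm and neurogenic ectoderm lists without one here include Mef2, tin, rho, vnd, brk and sog, which are not analysed here. A list is described by its median, by its members past 2-fold and by the number of 10000 random gene lists of the same size with a median as extreme. The random lists were not matched on expression, which the table does not give, and genes are not replicates. Median and mean differed in sign for segmentation genes in pipe against Toll10b (0.49 and -0.05), for later neural and homeotic genes in Tollrm9/rm10 against Toll10b (0.13 and -0.21), and for cellularisation (-0.14 and 0.08) and antimicrobial genes (0.07 and -0.02) in pipe against Tollrm9/rm10.

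A probe set was called highest or lowest in a genotype when both comparisons with that genotype showed at least 2-fold. Genes named in the text are the 8 with the largest ratio in each direction of each comparison whose direct and inferred ratios were both at least 2-fold in the same direction, the 5 leading each class, and for each list up to 4 members (2 for check lists) with the largest pipe against Toll10b ratio, plus Tl, pip, twi, sna, zen and dpp. Further members of the mesoderm, neurogenic, dorsal ectoderm, amnioserosa, endoderm and blood cell, segmentation and tracheal lists were named after their values were seen. Among these are ths, Dr, T48, peb, Pxn, fkh, slp2 and salm.

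The functions were tested on simulated data: signed, rounded folds for 13966 probe sets with the spread of the non-fly controls and 200 probe sets raised in pipe. Of those raised 2-fold 50.0% were placed highest in pipe, of those raised 4-fold 84.0%, and of those raised 8-fold and 16-fold 100%. Of unchanged ones 5.16% were. Each simulated genotype had 1 normal value per probe set, so the 3 simulated ratios closed the loop up to rounding, unlike most fly probe sets. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were median-centring, other fold limits, the inferred and least squares ratios, equal spread of the columns, genes in place of probe sets and, added after seeing the data, only probe sets closing the loop within 0.5 and only probe sets without the suffixes s, f, i and r, which mark shared or family matches, incomplete sets or relaxed rules.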

Results

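Dorsal, the NF-kB family transcription factor that patterns the dorsoventral axis of the fly embryo, enters ventral nuclei in response to the receptor Toll. The study compared total RNA of Drosophila melanogaster embryos, staged at 2 to 4 hours, from 3 maternal genotypes that differ in nuclear Dorsal. Embryos from pipe mothers keep Dorsal in the cytoplasm, Tollrm9/rm10 embryos have low or intermediate nuclear Dorsal, and Toll10b embryos have uniformly nuclear Dorsal. The question was which genes respond at which Dorsal level. There were 3 comparisons, 1 for each pair of genotypes, each deposited as 1 signed fold change for each of 13966 fly probe sets. The deposited table holds no replicate values, so no difference below has an error from replicates or a p-value. How many arrays stand behind each fold is not stated. Each Dorsal level is represented by 1 genotype. Its effect therefore cannot be told apart from other differences between the fly lines or their embryo collections. Positive values were read as higher in the genotype named first in the sample's title. This direction is likely rather than stated. It rests on the title order and on twi and sna, textbook genes activated by Dorsal, and zen and dpp, textbook genes repressed by it. With the opposite reading every "higher" below becomes "lower".

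The background of the measurement came from 32 control probe sets for targets that are not fly genes (bacterial spike-ins, yeast and mouse sequences). Of these, 3 differed at least 2-fold between Tollrm9/rm10 and Toll10b (9.38%, exact 95% binomial interval 1.98 to 25.02%), 8 between pipe and Toll10b (25.0%, 11.46 to 43.4%) and 7 between pipe and Tollrm9/rm10 (21.88%, 9.28 to 39.97%). Their largest folds were 2.6, 3.0 and 2.9 in the same order. A fold of 2 to 3 for a single probe set is therefore within what control probe sets showed. The number of probe sets limits this estimate, and the signal intensity behind each fold is unknown.

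The gene products that set the genotypes were read first. Tl, which encodes the Toll receptor (probe set 151935_at), was 7.9-fold higher in Toll10b than in Tollrm9/rm10 and 7.0-fold higher in pipe than in Tollrm9/rm10, while pipe and Toll10b differed 1.5-fold. The transcript of pip, a sulfotransferase gene that acts in the mother's ovary (143305_at), differed by 1.5-fold or less in all 3 comparisons. Neither gene checks the labels, since the Toll alleles alter a receptor whose transcript need not be lost and pipe acts before the embryo forms.

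Pipe embryos against Toll10b embryos set no nuclear Dorsal against nuclear Dorsal throughout. Genes of the dorsal ectoderm were higher in pipe, and genes of the mesoderm were higher in Toll10b. Of 14 measured dorsal ectoderm genes, 13 were at least 2-fold higher in pipe and none was 2-fold higher in Toll10b, with a list median of 2.32 on the log2 scale, and 0 of 10000 random gene lists of the same size had a median as high. Doc1, a T-box transcription factor gene (144254_at), was 28.6-fold higher in pipe. The homeobox gene zen (143420_at) was 21.9-fold higher, and tld, encoding a protease that releases Dpp from its inhibitor (143378_at), was 11.4-fold higher. C15 was 6.8-fold, dpp, the fly BMP ligand, 5.1-fold and tsg 4.7-fold higher in pipe. The exception was emc, 1.3-fold higher in pipe. Of 11 measured amnioserosa genes, most of them also in the dorsal ectoderm list, 9 were at least 2-fold higher in pipe. Of the 3 that are not in the dorsal ectoderm list, the TNF ligand gene egr (146921_at) was 11.9-fold higher in pipe, peb 1.5-fold and Kr 1.1-fold, and the inferred ratio for peb had the opposite sign. Of 11 Dpp signalling genes, 5 were at least 2-fold higher in pipe and 1, gbb, was 4.7-fold higher in Toll10b (median 0.85, 7 of 10000 random lists as high). Of those 5, dpp, tld and tsg are also dorsal ectoderm genes, and the median was 0.26 with only the probe sets whose 3 ratios close the loop within 0.5 on the log2 scale. Segmentation genes, chosen as a group not defined by the dorsoventral axis, had a median of 0.49 (94 of 10000 random lists as high) but a mean of -0.05. Of 17, 1 was at least 2-fold higher in pipe and 3 at least 2-fold higher in Toll10b.

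Of 8 measured mesoderm genes, 5 were at least 2-fold higher in Toll10b than in pipe and none the other way, with a list median of -2.56 on the log2 scale and 0 of 10000 random lists as low. With closing probe sets only the median was -0.85. The basic helix-loop-helix gene twi (143396_at) was 31.3-fold higher in Toll10b. Mdr49, an ABC transporter gene (141779_at), was 24.1-fold higher, sna, a zinc finger repressor gene (143356_at), 14.2-fold, and htl, an FGF receptor gene (154602_at), 7.7-fold higher. T48 was 4.5-fold higher. Early mesoderm genes that were not 2-fold higher in Toll10b were zfh1 (1.8-fold higher in Toll10b), fog (1.1-fold higher in Toll10b) and bap (1.9-fold higher in pipe). Some members of this list were recognised as Dorsal targets in work that may have included these samples, so the list is not independent evidence of its direction. The neurogenic and dorsal ectoderm lists were likewise chosen for known responses to Dorsal. In addition, twi, sna, zen and dpp, members of the mesoderm and dorsal ectoderm lists, were a basis for the direction of the columns. The counts of random lists for all 3 lists are therefore descriptions and not independent evidence. Of 7 measured muscle structural genes, 3 were at least 2-fold higher in Toll10b, among them Mlc2 (7.0-fold) and Tm2 (3.4-fold), and none was 2-fold higher in pipe. The median was -0.99, with 292 of 10000 random lists as low. Of 9 measured genes of endoderm and blood cell progenitors, 4 were at least 2-fold higher in Toll10b, among them gcm, a glial and blood cell regulator (5.3-fold), and 1, ush, was 6.0-fold higher in pipe. Neurogenic ectoderm genes did not separate these 2 genotypes as a list (median -0.42, 2264 of 10000 random lists as low). For ind (3.9-fold higher in Toll10b), pyr (3.6-fold) and SoxN at 142903_at (3.1-fold), the ratio inferred from the other 2 comparisons had the opposite sign.

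**Figure D1:**
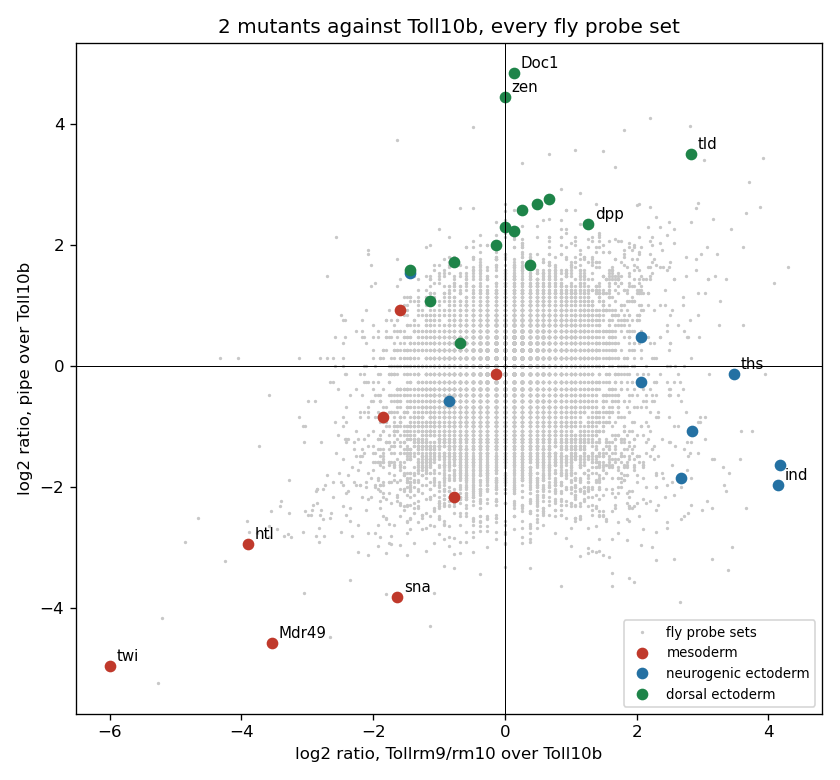
Each point is 1 fly probe set; the x axis is the log2 ratio of Tollrm9/rm10 over Toll10b and the y axis the log2 ratio of pipe over Toll10b, with members of 3 gene lists in colour and no replicate error available. Mesoderm genes such as twi (63.8-fold and 31.3-fold higher in Toll10b) lie at the lower left, zen and Doc1 at the top near 0 on the x axis, and ind and ths at the far right.

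Outside those lists, genes with large folds whose inferred ratio was also at least 2-fold in the same direction went both ways. Higher in pipe were CG9184 (15.7-fold), Ect3 (15.5-fold), a beta-galactosidase gene, Osi6 of the Osiris gene cluster (11.7-fold), and TwdlM (17.2-fold), which encodes a Tweedle cuticle protein. Higher in Toll10b were CG8788 (19.7-fold), CG16868 (15-fold), nemy (13.7-fold), CG12177 (13.5-fold) and TwdlJ (13.5-fold). The named probe sets of TwdlM, TwdlJ and nemy have the suffixes i and r, which on this type of array mark an incomplete set or relaxed rules of probe choice. The other probe set of TwdlM was 3.9-fold higher in pipe, that of TwdlJ was at 1.0-fold, and that of nemy was 1.6-fold higher in Toll10b. Over all probe sets, 1236 were at least 2-fold higher in pipe and 2979 at least 2-fold higher in Toll10b (70.7% of those past 2-fold). Among probe sets whose 3 ratios closed the loop within rounding the counts were 390 and 450. Past 2-fold in either direction were 30.2% of 13966 (29.42 to 30.95%), against 25.0% of the control probe sets. At 3-fold the counts were 327 and 1224, 11.1% against 1 of 32 control probe sets (3.12%, 0.08 to 16.22%).

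Tollrm9/rm10 embryos against Toll10b embryos set intermediate against high nuclear Dorsal. Genes of the neurogenic ectoderm were higher in Tollrm9/rm10 and genes of the mesoderm were higher in Toll10b. Of 8 measured neurogenic ectoderm genes, 6 were at least 2-fold higher in Tollrm9/rm10 (list median 2.37 on the log2 scale, 0 of 10000 random lists as high). The Sox gene SoxN was 18.0-fold higher at 142903_at and 7.2-fold at 151713_at. The homeobox gene ind (144092_at) was 17.8-fold, the FGF ligand genes ths (147037_at) and pyr (147034_at) were 11.1-fold and 6.4-fold, and l(1)sc and Dr each 4.2-fold higher. The inferred folds, in the same direction, were smaller for all but l(1)sc, which stayed at 4.2. They were 3.6 and 5.4 for SoxN at its 2 probe sets, 4.5 for ind, 5.7 for ths, 2.3 for Dr and 1.7 for pyr, under 2-fold. The 2 others were higher in Toll10b, mirr by 2.7-fold and aos by 1.8-fold. Of 8 mesoderm genes, 6 were at least 2-fold higher in Toll10b and none in Tollrm9/rm10 (median -1.74, 0 of 10000 random lists as low). These included twi (63.8-fold), htl (14.9-fold), Mdr49 (11.6-fold), zfh1 (3.6-fold), sna (3.1-fold) and bap (3.0-fold). Their inferred folds, in the same order and direction, were 26.1, 10.8, 3.2, 4.0, 2.8 and 2.4. The gcm gene was 11.7-fold and Mlc2 6.7-fold higher in Toll10b. The 9 endoderm and blood cell genes had a median of -0.68 (186 of 10000 random lists as low), which was -0.11 from the inferred ratios. Of these 9, 2 were at least 2-fold higher in Toll10b, gcm and Pxn (3.6-fold), and 2 at least 2-fold higher in Tollrm9/rm10, fkh (3.3-fold) and hkb (2.1-fold).

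Dorsal ectoderm genes did not separate these 2 genotypes as a list. The median was 0.07, 11 of 14 were under 2-fold, and zen (1.0-fold) and Doc1 (1.1-fold) were nearly equal. Exceptions were tld, 7.1-fold higher in Tollrm9/rm10, dpp, 2.4-fold higher there, and Doc2, 2.7-fold higher in Toll10b. For dpp the inferred ratio was 1.4-fold in the same direction. Segmentation genes were at least 2-fold higher in Tollrm9/rm10 for 7 of 17 and in Toll10b for none (median 0.68, 31 of 10000 random lists as high). The pair-rule and segment polarity genes gsb (12.7-fold), slp2 (4.6-fold) and en (3.0-fold) were among them. For gsb, the largest of these folds, the inferred ratio was 2.3-fold in the same direction.

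Genes outside the lists with large folds, and with an inferred ratio of at least 2-fold in the same direction, included Cyp310a1, a cytochrome P450 gene (28.9-fold), Phyhd1 (25.2-fold), net, a basic helix-loop-helix gene (20.1-fold), GstD1, a glutathione S-transferase gene (16.6-fold), hll (15-fold) and CG14036 (14.8-fold), all higher in Toll10b. Higher in Tollrm9/rm10 were CG13921 (16.9-fold), Meltrin, a metalloprotease gene (15.4-fold), Ptr (15.1-fold), Kpc2 (14.6-fold) and tkv, which encodes a type I receptor for Dpp (13.1-fold). The other probe set of tkv showed 1.3-fold in the same direction, that of Meltrin 2.1-fold in the same direction, and that of Kpc2 1.2-fold in the opposite one. In all, 1818 probe sets were at least 2-fold higher in Tollrm9/rm10 and 1469 in Toll10b, 23.5% of the total against 9.38% of control probe sets. The ratio inferred from the other 2 comparisons gave 684 and 579, so these counts depend on which ratio is used.

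Pipe embryos against Tollrm9/rm10 embryos set no nuclear Dorsal against low or intermediate nuclear Dorsal. All 14 measured dorsal ectoderm genes were at least 2-fold higher in pipe by the deposited ratio (median 2.36, 0 of 10000 random lists as high), led by Doc1 (32.5-fold) and zen (22.7-fold), with pnr at 6.3-fold, ush at 5.2-fold and dpp at 3.6-fold. For tld, 4.4-fold higher in pipe, the inferred ratio was 1.6-fold in the same direction. Of 8 neurogenic ectoderm genes, 6 were at least 2-fold higher in Tollrm9/rm10 (median -2.08, 0 of 10000 random lists as low). These were ind (17.6-fold), SoxN (11.2-fold and 11.4-fold at its 2 probe sets), ths (6.3-fold), pyr (6.0-fold), l(1)sc (3.0-fold) and Dr (2.8-fold), while mirr was 3.8-fold higher in pipe. Mesoderm genes divided. Mdr49 (7.5-fold), sna (5.0-fold) and T48 (4.1-fold) were higher in Tollrm9/rm10, and bap (4.6-fold) and zfh1 (2.2-fold) were higher in pipe. Under 2-fold were twi (1.2-fold), htl (1.4-fold) and fog (1.0-fold). The list median was -0.13, with 5471 of 10000 random lists as low. Of 17 segmentation genes, 7 were at least 2-fold higher in Tollrm9/rm10 and none in pipe (median -0.58, 1000 of 10000 random lists as low). Among them were hkb at 4.6-fold and Kr at 2.0-fold. Of 13 Toll pathway genes, 5 were at least 2-fold higher in pipe and none in Tollrm9/rm10, among them Tl (7.0-fold), snk (2.7-fold) and Myd88 (2.6-fold). As a list they did not shift: the median was 0, at percentile 67.5 of random lists, and 8 were under 2-fold. The folds of snk and Myd88 lay within the 2.9-fold that control probe sets reached in this comparison.

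Other genes with large folds in this comparison were Ect3 (20.9-fold), TwdlM (15.5-fold), egr (11.4-fold), TwdlN (11.2-fold), NdufV3, a mitochondrial complex I gene (11-fold), and Osi6 (10.8-fold), all higher in pipe. The other probe set of TwdlM was 3.9-fold and that of TwdlN 1.9-fold higher in pipe. Higher in Tollrm9/rm10 were CG16868 (16.3-fold), AlaRS, an alanyl-tRNA synthetase gene (13.3-fold), CG13605 (12.2-fold), Gad1, which encodes glutamate decarboxylase (11.9-fold), uncNacbeta (11.9-fold) and gsb (11.6-fold). Of 7 measured tracheal and salivary gland genes, 4 were at least 2-fold higher in Tollrm9/rm10 (median -1.14, 1.6% of random lists lower), with vvl at 8.0-fold and salm at 4.2-fold. Their median was -0.38 with closing probe sets only and -0.56 from the inferred ratios. Counts were 1393 probe sets at least 2-fold higher in pipe and 3198 in Tollrm9/rm10, 32.9% against 21.88% of control probe sets. Among probe sets whose 3 ratios closed the loop within rounding they were 528 and 524. The array's GAPDH controls were 2.1-fold (3' end) and 1.3-fold (middle) higher in pipe but 1.5-fold higher in Tollrm9/rm10 at the 5' end, and its 18S rRNA controls were 2.7-fold (3' end) and 1.8-fold (5' end) higher in Tollrm9/rm10 and 1.3-fold higher in pipe in the middle.

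**Figure D2:**
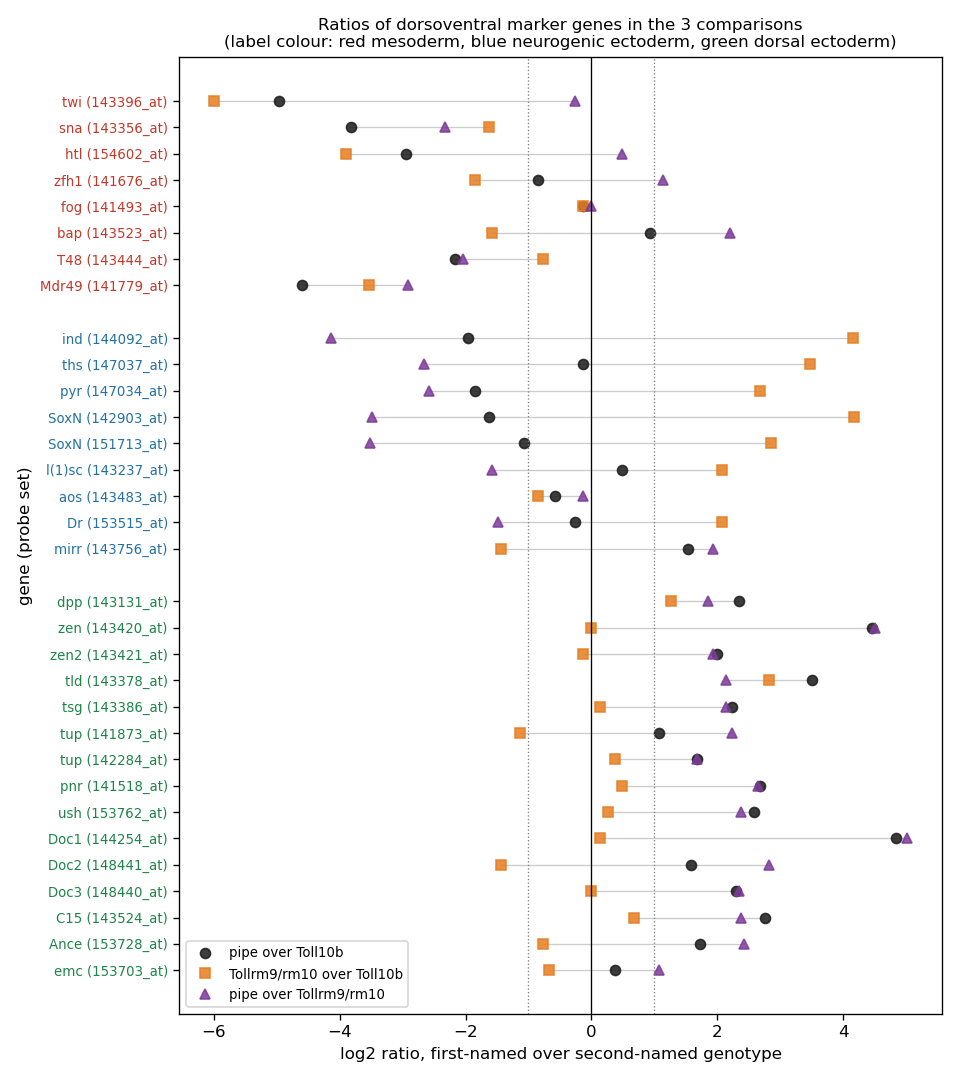
Rows are the measured probe sets of 3 gene lists and the x axis is the log2 ratio of the first-named over the second-named genotype, with 1 symbol for each comparison, dotted lines at 2-fold and no replicate values. Dorsal ectoderm genes lie to the right for both pipe comparisons, neurogenic genes such as ind lie far right for Tollrm9/rm10 over Toll10b and far left for pipe over Tollrm9/rm10, and twi and htl lie far left in both comparisons with Toll10b.

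The 3 comparisons together placed genes by the genotype in which they were highest or lowest, with at least 2-fold in both comparisons that contain it. Highest in Toll10b were 603 probe sets, led by twi, Mdr49, CG12177, htl and Cyp310a1. Highest in Tollrm9/rm10 were 917, led by ind, gsb, SoxN, Meltrin and uncNacbeta. For uncNacbeta the inferred ratio of Tollrm9/rm10 over Toll10b was 1.3-fold, under the limit, where the direct one was 8.8-fold. Highest in pipe were 687, led by Doc1, zen, TwdlM, Ect3 and egr. Lowest in pipe were 2332, led by CG16868, TwdlJ, AlaRS, Gad1 and nemy. Lowest in Tollrm9/rm10 were 416, led by GstD1, net, Spase12, Tl and NdufV3, and lowest in Toll10b 359, led by Ptr, tkv, Obp99a, tld and CG9184. Probe sets graded from pipe lowest to Toll10b highest numbered 295 and include sna and Mdr49, whose 3 folds step in 1 direction. Those graded the other way numbered 88 and include dpp and tld. For each, 1 step was under 2-fold from the inferred ratio. For dpp, Tollrm9/rm10 over Toll10b was 2.4-fold directly, within the 2.6-fold that controls reached, and 1.4-fold inferred. For tld, pipe over Tollrm9/rm10 was 1.6-fold inferred. No simulated size was made for the graded groups.

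Comparisons that share a genotype share its chance values. With the spread of the control probe sets and no real difference, simulated class sizes were 671 for highest in pipe, 46 for highest in Tollrm9/rm10, 160 for highest in Toll10b, 702 for lowest in pipe, 64 for lowest in Tollrm9/rm10 and 185 for lowest in Toll10b. Independent lists of the observed sizes would overlap in 123, 416, 313, 682, 147 and 161 probe sets, in the same order. The number highest in pipe was near its simulated size. The simulation was 1 draw of normal values, 1 per genotype and probe set, with the spread of the 32 controls. Its ratios therefore closed the loop up to rounding, while only 42.7% of fly probe sets closed within rounding. The simulated sizes are thus a rough guide and not a test. Of the 32 control probe sets themselves, 4 were lowest in pipe (12.5%, 3.51 to 28.99%), against 16.7% of fly probe sets, 1 was highest in pipe, 1 highest in Toll10b and none in the other classes. Part of every excess may come from the shared measurements. At 3-fold the classes held 159, 269, 152, 924, 67 and 83 probe sets.

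The remaining lists served as checks of stage, of other tissues and of stress. Of 7 measured cellularisation genes, slam (2.6-fold) and nullo (2.2-fold) were higher in pipe than in Toll10b and the other 5 were under 2-fold. Of 5 housekeeping genes, Tbp was 2.2-fold higher in Toll10b than in pipe, and Gapdh1 (154244_at) was 1.6-fold higher in pipe. The array's own GAPDH controls went the other way, 1.6-fold (3' end), 1.7-fold (middle) and 3.3-fold (5' end) higher in Toll10b, and its 18S rRNA controls were 2.9-fold, 1.5-fold and 1.6-fold higher in Toll10b in the same order. Among 8 later neural and homeotic genes, 3 were at least 2-fold higher in Toll10b than in pipe and none at least 2-fold higher in pipe. The list median was -0.81 on the log2 scale, at percentile 4.2 of random lists and so inside their central 95%. The 3 included pros, 2.7-fold higher in Toll10b than in pipe. However, pros was highest in Tollrm9/rm10, 2.9-fold above Toll10b and 6.6-fold above pipe. The inferred folds for these were 2.4 and 7.8 in the same direction. Of 6 antimicrobial genes, Def was 2.7-fold higher in Toll10b than in pipe and CecB 2.3-fold higher in pipe. Of 13 Toll pathway genes, 1, Myd88, was at least 2-fold higher in pipe than in Toll10b (2.4-fold) and none at least 2-fold higher in Toll10b. Of 8 pole cell genes 1, piwi, was at least 2-fold higher in Toll10b (2.3-fold), and of 5 heat shock genes 1, Hsp68, was (2.2-fold). Of 5 ventral midline genes, E(spl)m7-HLH reached 2.0-fold higher in Toll10b than in pipe, and sli was 3.2-fold higher in Tollrm9/rm10 than in Toll10b. Of 9 FGF and EGF signalling genes, 4 were at least 2-fold higher in Toll10b than in pipe, among them sty (3.8-fold) and btl (2.5-fold). Of 54 list medians over all lists and comparisons, 13 fell outside the central 95% of random lists. The medians are not independent trials, since lists share genes and comparisons share genotypes, so 13 cannot be set against a chance of 5%. The 13 include medians of the mesoderm, neurogenic ectoderm, dorsal ectoderm and amnioserosa lists, which are not checks. They also include segmentation genes, chosen as a group not defined by the dorsoventral axis, in both comparisons with Toll10b. The rest are Dpp genes in pipe against Toll10b, endoderm and blood cell genes in Tollrm9/rm10 against Toll10b, and tracheal genes in pipe against Tollrm9/rm10.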

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

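Fold limits set the counts. At 1.5-fold the counts in Tollrm9/rm10 against Toll10b were 3673 higher in Tollrm9/rm10 and 3159 higher in Toll10b, and at 3-fold 642 and 413. In pipe against Toll10b they were 2917 in pipe and 4760 in Toll10b, and at 3-fold 327 and 1224. In pipe against Tollrm9/rm10 they were 3089 and 5072, and 340 and 1400. The ratio inferred from the other 2 comparisons gave 684 and 579 for Tollrm9/rm10 against Toll10b, and least squares gave 975 higher in Toll10b. Keeping only probe sets that close the loop within 0.5 on the log2 scale, an alternative chosen after seeing the data that by construction uses fewer probe sets, gave 581 and 555, then 805 and 1414, and 1554 higher in Tollrm9/rm10 than in pipe. The classes at 1.5-fold held 1841 (highest in pipe), 2101 (highest in Tollrm9/rm10), 1544 (highest in Toll10b), 3897 (lowest in pipe), 1189 (lowest in Tollrm9/rm10) and 1125 (lowest in Toll10b). At 3-fold they held 159, 269, 152, 924, 67 and 83, and with closing probe sets only 452, 165, 104, 1099, 215 and 136. Median-centring, equal spread, genes in place of probe sets and leaving out probe sets with the suffixes s, f, i and r kept every 2-fold count within 1.5 times where they were run. The requirement of a value in all 3 comparisons removed no probe set. In pipe against Toll10b the share higher in Toll10b was 70.7% as deposited and 63.2% after centring. Of the lists outside the central 95% of random lists, none changed sign. With closing probe sets only the mesoderm median for pipe against Toll10b was -0.85 and the Dpp median there 0.26. From inferred ratios the endoderm and blood cell median for Tollrm9/rm10 against Toll10b was -0.11, the neurogenic median for pipe against Tollrm9/rm10 was -2.97, and the tracheal median there was -0.56 (-0.38 with closing probe sets). Of named ratios of at least 2-fold, 4 changed sign, all in pipe against Toll10b from the inferred ratio: ind (0.016), gsb (0.13), SoxN at 142903_at (0.68) and pyr (0.093), all deposited as higher in Toll10b, so no order of pipe and Toll10b can be read for them, and the cause was not tested. Ratios under 2-fold changed sign too, among them twi in pipe against Tollrm9/rm10 (-0.26 deposited, 1.03 inferred), CG12177 there (0.38 and -0.70), and Meltrin, ths, Dr and slp2 in pipe against Toll10b. Of the gene ratios computed under the inferred ratio, 225 moved by less than the SD of the non-fly controls, 98 by more without changing sign past 2-fold, and centring moved none of 327 by that much. No paired analysis was possible because each comparison has 1 value. The limma loop was not run. Signal over background is unknown, so how far it limits single folds cannot be given.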

Other observations

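The first 2 tests of the pipe skew, the control test of the loop and both tests of gene families were chosen, and the simulation for the RNA test was added, after the result was seen. Beyond the fixed lists, glutathione S-transferase GstD1, the helix-loop-helix gene net, the signal peptidase gene Spase12 and the complex I gene NdufV3 had, like Tl, their lowest level in Tollrm9/rm10. GstD1 was 16.6-fold higher in Toll10b and 10.2-fold higher in pipe than in Tollrm9/rm10, and 1.1-fold apart between pipe and Toll10b. Spase12 was 7.0-fold and 8.2-fold higher in the same comparisons. Another group was lowest in Toll10b: Ptr, 15.1-fold higher in Tollrm9/rm10 and 10.8-fold higher in pipe, and Obp99a, 8.1-fold and 10.6-fold higher. For both genes the inferred folds (14.0 and 11.6, 8.2 and 10.5) lay near the direct ones.

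Over all 6 classes together, genes that neighbour each other on the chromosome shared a class at the upper edge of the central 95% of chance. Over 10764 genes in order, 292 neighbouring pairs of genes with no overlap shared at least 1 class. The central 95% of 10000 shufflings was 237 to 293 (one-sided permutation p = 0.0299). Without pairs of 1 symbol family and without probe sets with the suffixes s, f, i and r, 266 pairs did (227 to 282, one-sided permutation p = 0.209). Whether neighbours share classes in general therefore stays open. The class highest in Tollrm9/rm10 had 42 pairs against a median of 28 (one-sided permutation p = 0.0043, Benjamini-Hochberg 0.0258 over 6 classes) and 41 against 27 after those exclusions (permutation p = 0.0050, adjusted 0.030). Gene copies stay open there, since symbols cannot reveal them for the 23 of the 41 pairs in which a gene has only a number for a name, and since the related FGF ligand genes pyr and ths are 1 of the pairs.

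Other neighbours shared a class in pipe. Both zen2 and zen, Doc2 and Doc1, and tok and tld were highest in pipe, a class whose 24 pairs did not exceed chance (permutation p = 0.1071, adjusted 0.2142).

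More probe sets were lower than higher in pipe, 2979 against 1236 at 2-fold relative to Toll10b. The fly controls were mixed. GAPDH and 18S rRNA controls were lower in pipe than in Toll10b, by 1.5-fold to 3.3-fold. Against Tollrm9/rm10, 5' GAPDH was 1.5-fold lower in pipe, but 3' and middle GAPDH were 2.1-fold and 1.3-fold higher. The 18S rRNA controls divided there too (2.7-fold and 1.8-fold lower, 1.3-fold higher in pipe). Actin and eIF-4a controls differed by 1.3-fold or less in both pipe comparisons. A constant scaling alone was argued against. Of probe sets past 2-fold against Toll10b, 63.2% were still lower in pipe after median-centring (95% interval 61.7 to 64.7%). That interval covers counting of probe sets only, and centring cannot remove scaling that varies with signal, which was not tested. Weak signals near the noise floor stay open, because the table gives no signal and how well the 3 ratios close does not measure it: 53.6% were lower among probe sets closing within rounding (50.1 to 57.0%; against Tollrm9/rm10 49.8%, 46.7 to 52.9%) and 63.7% among those closing within 0.5 on the log2 scale (against Tollrm9/rm10 61.9%). Closing itself fell from 52.6% of probe sets under 2-fold to 19.9% of those past it, though at 2-fold to under 3-fold 52.2% of the closing and 70.3% of the other probe sets were lower. In 946 genes with 2 probe sets both were 2-fold lower in 51, within the 41 to 63 of random pairings, so a difference of the RNA was not seen there but stays open: if the excess were real and probe sets agreed as weakly as in the 4 directions without an excess of lower values in pipe, 12.8% of 10000 simulated counts would pass that range.

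That the 3 ratios often close the loop is consistent with 1 measurement per genotype shared by the comparisons. Direct and inferred ratios of the 32 non-fly control probe sets were correlated across probe sets. For pipe against Toll10b, the comparison chosen for the test with a bar of 0.8, r was 0.936. For pipe against Tollrm9/rm10 r was 0.893, and for Tollrm9/rm10 against Toll10b it was 0.757, under that bar. Control targets whose amounts differ between the RNA samples would also give such correlations, even on separate arrays. The control test therefore cannot tell that case from a shared measurement. No biological explanation was tested for this pattern.

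Probe sets of the same gene agreed little. Across 946 genes with 2 probe sets r was 0.17 for Tollrm9/rm10 against Toll10b, 0.04 for pipe against Toll10b and 0.09 for pipe against Tollrm9/rm10. In the 176 genes whose probe sets both closed the loop within rounding r was 0.47, 0.13 and 0.26. Both probe sets were 2-fold higher in pipe than in Tollrm9/rm10 in 15 genes, against 3 to 12 in random pairings (one-sided permutation p = 0.0034, adjusted 0.0204 over 6 directions), and 2-fold higher in Toll10b than in Tollrm9/rm10 in 17, against 4 to 16 (permutation p = 0.0133, adjusted 0.0399), while the other 4 directions stayed within the random range. The fly GAPDH control was 3.4-fold higher in Toll10b than in Tollrm9/rm10 at its 3' probe set, 2.0-fold in the middle and 4.9-fold at its 5' probe set. In pipe against Tollrm9/rm10 its 3' end was 2.1-fold higher in pipe and its 5' end 1.5-fold higher in Tollrm9/rm10. The 18S rRNA controls were 1.5-fold (3' end) and 2.2-fold (middle) higher in Toll10b than in Tollrm9/rm10, and 1.1-fold higher in Tollrm9/rm10 at the 5' end. The eIF-4a controls differed by 1.2-fold or less in Tollrm9/rm10 against Toll10b.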
